A study of Mus musculus with 8 samples.

How the data were processed

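RNA-seq of 8 libraries was analysed. Per the labels, each library came from AH1 tetramer-positive CD8+ T cells of BALB/c mice, sorted live on a FACSAria III. The series divides them by genotype (wild type or Cd69 knockout, called Cd69-deficient here) and by sorted subset (named stem-like and term diff in the labels, the latter written term-diff here). Each of the 4 groups held 2 libraries. The labels do not give the tumour, the sex or number of mice, the sort gates, or whether libraries of different groups came from the same mouse. Libraries had been made from total RNA with a low-input stranded kit (SMARTer, Pico Input) and read single-end on a NextSeq500.

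The deposited files were gene tables laid out as Cufflinks writes them, 1 per library, and the authors gave expression in FPKM (fragments scaled by transcript length and library total) with the limits of a confidence interval in the same unit. The submitters' processing notes name bcl2fastq 2.20, Bowtie2 2.3.4, TopHat 1.3.2 and Cufflinks 2.2.1 with the mouse build mm10, without saying what each step did. The annotation, the strand setting and the total used for the FPKM were not stated by the authors. Each table held 23746 rows and 23284 distinct symbols; 708 rows carried a symbol listed at more than 1 locus and were kept apart. Of all values, 5 (in 3 genes) had a status other than OK, and those genes were left out.

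No read counts were in these tables. The width of each confidence interval of the deposited FPKM implied a number of fragments, the square of 2 times the FPKM divided by the distance to its upper limit. Among rows with fewer than 15 implied fragments, 63.6% to 65.5% per library lay within 0.05 of a whole number. These implied fragments summed to 2055402 to 2591061 per library. They were taken as counting error alone and hold no variation between mice. Why the remaining low rows lay further from a whole number was not tested, so implied fragments are approximate. Between 8911 and 9225 rows per library reached 1 FPKM as deposited. Sums of the deposited FPKM ran from 282589 to 919280, and 827 rows of small RNA held 56.0% to 84.4% of each sum but 5.52% to 9.53% of the implied fragments.

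Values were used as deposited, without further scaling, as log2(FPKM + 1). Genes with at least 1 FPKM in at least 2 libraries were kept, which left 9782. A linear model of 4 group means was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend), with 4 residual degrees of freedom and a prior of 4.2. Comparisons were term-diff minus stem-like within each genotype, Cd69-deficient minus wild type within each subset and averaged over subsets, and the interaction (the genotype difference in term-diff minus that in stem-like). Tests were 2-sided, adjusted by Benjamini and Hochberg over all genes kept, with a threshold of 0.05. All 8 libraries shared 1 estimate of the spread per gene.

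Gene lists were tested with camera of limma at its preset correlation of 0.01 between genes, adjusted over the lists of each comparison. The same test with an estimated correlation, and fry, stood beside it. Of 20 lists, 17 had at least 3 genes kept and were tested: stem and progenitor, terminal exhaustion, cytotoxic effector, tissue residency, egress and recirculation, early T cell receptor response, proliferation, interferon response, chemokines and cytokines, glycolysis, oxidative phosphorylation, heat shock, and markers of CD8 T cells, myeloid cells, CD4 and regulatory T cells, NK cells, and tumour and stroma. The neutrophil, B cell and erythroid marker lists had too few. Several lists share members, such as Tcf7 and Ccr7 in both the stem and egress lists. The mouse symbols Trac, Trbc1 and Trbc2 had no row in the tables.

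Comparisons, lists, thresholds and the rule for the genes named were set before the data were examined. That rule took Cd69 in every library, and the 10 largest rises and 10 largest falls past the threshold with a group mean of at least 5 FPKM as deposited and no overlap between libraries. It also took up to 4 members per list, the genes with the smallest p where fewer than 10 passed, and a fixed set in each genotype comparison (Tcf7, Slamf6, Havcr2, Pdcd1, Tox, Gzmb, Ifng, S1pr1 and Klf2, beside a gene that is not reported here). In the closing part it took genes within 10 Mb of Cd69. Unnamed gene models needed no name under the rule, though some are named, and of the members a rule took, some were left unnamed for length. Other genes named in the text, such as Klra3 between the genotypes, were chosen after their values were seen.

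Alternatives changed 1 choice at a time: pseudocounts of 0.1 and 5; no filter, or at least 5 FPKM of the deposited values; median-of-ratios scaling, quantile normalization, or rescaling each library to an equal sum; robust, untrended and library-weighted fits; the replicate number as a block; only the groups compared in the fit; rows of other status kept; thresholds of 0.1 or with an absolute log2 fold change of at least 1; and each library left out in turn. Added after the data were seen were leaving out small RNA rows, requiring at least 10 implied fragments in 2 libraries, leaving out both wild-type replicate 2 libraries, voom of limma on the implied fragments, and an additive model of subset and genotype.

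The model was tested on simulated data in which 100 genes each with a mean above 1 on the log2 scale were given a log2 change of 1 or 2, among 9782 in all. In a comparison of 2 libraries with 2 shaped as the stem-like genotype comparison, 73% and 96% of these were called, with 10 unchanged genes called. For the difference averaged over subsets the shares were 94% and 100%, with 14 unchanged genes called, and for the subset comparison in wild type 71% and 99%, with 12. The simulated spread was that of the model, so these shares are an upper guide. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Exons, isoforms and sequence variants could not be examined in gene-level tables.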

Results

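The 8 libraries hold tumour-antigen-specific CD8+ T cells: the AH1 tetramer carries a peptide of the murine leukaemia virus envelope protein. They divide by genotype (wild type or Cd69-deficient) and by sorted subset (stem-like or term-diff), with 2 libraries per group. Fold changes below are differences on the log2(FPKM + 1) scale ± standard error, and levels are mean FPKM ± SD (n = 2).

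Cd69, an early activation receptor that holds T cells in tissue by opposing the egress receptor S1pr1, was at 22.5 and 23.4 FPKM in the wild-type stem-like libraries and 10.4 and 12.9 in wild-type term-diff. It was at 3.69 and 2.42 in Cd69-deficient stem-like and 2.21 and 2.43 in Cd69-deficient term-diff, so each genotype label fitted its library. Gene-level totals do not show which exons the remaining signal came from. Between genotypes Cd69 fell in stem-like (-2.58 ± 0.17, adjusted p = 0.00096) and in term-diff cells (-1.93 ± 0.17, adjusted p = 0.0096). The term-diff call ended without wild-type term-diff replicate 2 (adjusted p = 0.0547), Cd69-deficient term-diff replicate 1 (adjusted p = 0.0779) or replicate 2 (adjusted p = 0.0886). In wild type, Cd69 was also lower in term-diff than in stem-like (-0.93 ± 0.17, adjusted p = 0.011). That call ended without wild-type stem-like replicate 1 (adjusted p = 0.0521) or 2 (adjusted p = 0.0542) or term-diff replicate 1 (adjusted p = 0.0693). Xist, the RNA of the inactive X chromosome, was at 38.9 to 66 FPKM in all 8 libraries, and the Y-linked genes Ddx3y and Uty reached at most 0.0144 and 0.0218.

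**Figure D1:**
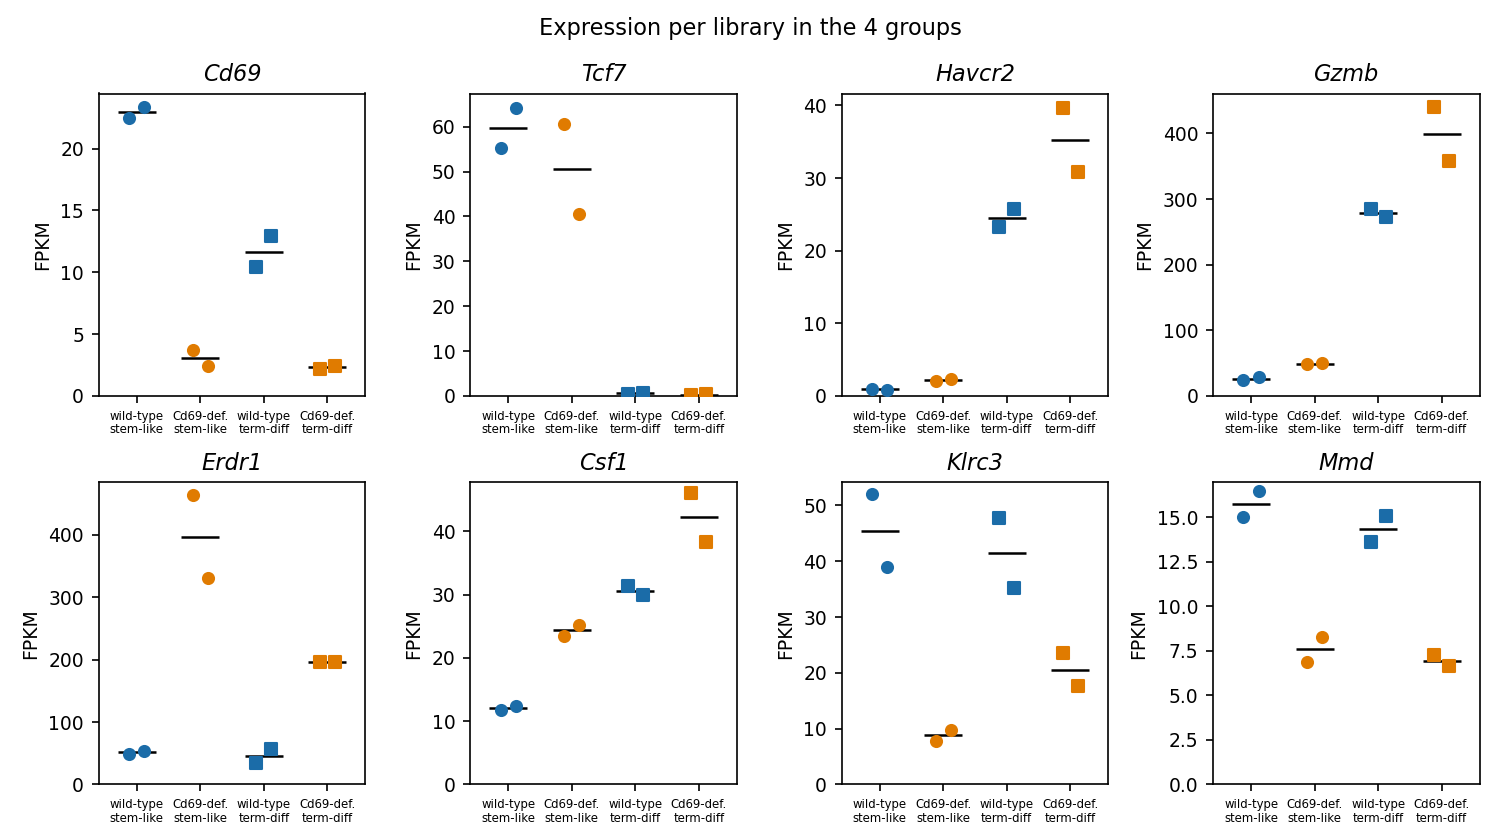
FPKM of Cd69, Tcf7, Havcr2, Gzmb, Erdr1, Csf1, Klrc3 and Mmd in each library (dots) with group means (bars, n = 2). Klrc3 has close paralogs, so its reads may be shared with them.

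In wild type, term-diff cells had far lower levels of Tcf7 than stem-like cells and higher levels of Havcr2 and Gzmb. Tcf7, the transcription factor of progenitor-like T cells, fell from 59.7 ± 6.3 to 0.65 ± 0.15 FPKM (-5.20 ± 0.19, adjusted p = 1.2e-05). Havcr2, the inhibitory receptor TIM-3, rose from 0.917 ± 0.099 to 24.6 ± 1.8 (3.74 ± 0.15, adjusted p = 1.3e-05). Gzmb, a granzyme of cytotoxic granules, rose from 26 ± 3.4 to 279 ± 8.3 (3.38 ± 0.17, adjusted p = 2.3e-05), and Ccl5, a chemokine, from 6.6 ± 0.68 to 176 ± 65 (4.49 ± 0.36). Also among the largest rises were Fcer1g (3.65 ± 0.17), a signalling chain of Fc receptors and Entpd1 (3.53 ± 0.17), the ectoenzyme CD39. Adam8 (3.35), a metalloprotease, Filip1 (2.96), Plac8 (2.77) and Ppp1r3b (2.73) followed. The falls included Dapl1 (-4.50), the lymph node homing receptor Ccr7 (-3.74), and Slamf6 (-3.66), a surface marker of progenitor cells. Others were Lrig1 (-3.44), Aff3 (-3.21), Cd83 (-3.03), Cyr61 (-2.92), the chemokine receptor Ccr6 (-2.89) and Rprl2 (-3.31). Rprl2, a small RNA gene, was uneven between replicates (814 ± 860 in stem-like). Its call ended without wild-type term-diff replicate 1 (adjusted p = 0.0965) or 2 (adjusted p = 0.0823).

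The sort gates are not given, so markers used in the sort may be among the leading genes and the lists. Their direction may then restate the sort. By list, 14 of 19 measured stem and progenitor genes fell and 0 rose (16 fell adjusted over the list alone, median -1.53), Il7r (-2.64) among them. Camera gave adjusted p = 4.31e-19 for this list, and adjusted p = 0.267 with an estimated correlation. Of 22 terminal exhaustion genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.33), such as Cxcr6 (2.11) and Prdm1 (1.78). The camera result was adjusted p = 0.000411, and adjusted p = 0.384 with an estimated correlation. In the proliferation list 18 of 29 rose and 0 fell (24 rose adjusted over the list alone, median 0.70), with camera adjusted p = 1.93e-10 and adjusted p = 0.384 with an estimated correlation. Mki67, a protein of dividing cells, went from 37.7 to 81.9 FPKM (1.09 ± 0.17), and the replication helicase subunit Mcm5 rose (0.98). Of 15 egress and recirculation genes 6 fell and 0 rose (8 fell adjusted over the list alone, median -0.50), such as the integrin Itgb7 (-1.98). Here camera had adjusted p = 2.21e-06, and adjusted p = 0.384 with an estimated correlation.

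Other lists did not pass as a whole in wild type by camera. By fry the cytotoxic (adjusted p = 0.00461), residency (adjusted p = 0.0142) and glycolysis lists (adjusted p = 0.0399) leaned up. CD4 and regulatory T cell markers leaned down by fry (adjusted p = 0.003). Of 23 cytotoxic effector genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.151), including the granzyme Gzmf (2.06) and the pore-former Prf1 (1.91). Tissue residency genes split into 7 of 14 that rose and 2 that fell (8 and 2 adjusted over the list alone, median 0.70, camera adjusted p = 0.0609). Cxcr6 rose, as did the integrin Itga1 (1.17) and Chn2 (1.48), while the chemokine Xcl1 fell (-2.11). Chemokines and cytokines went both ways (7 of 18 up and 8 down, 7 and 9 adjusted over the list alone, median -0.49, camera adjusted p = 0.189), with Ccl4 at 1.99 and Tnfsf11 at -2.27. In the early T cell receptor response list 4 of 26 rose and 5 fell (5 and 8 adjusted over the list alone), with Dusp5 at 1.65, Egr3 at -1.64 and Batf at -1.45. Its median was 0.04 and its mean -0.15 (camera adjusted p = 0.202).

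Glycolysis had 2 of 18 higher and 1 lower in term-diff (4 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.0666). The interferon list had 1 and 1 of 24 (1 and 1 adjusted over the list alone, median 0.16, camera adjusted p = 0.482). No member of the oxidative phosphorylation (35 genes, median 0.01, camera adjusted p = 0.949), heat shock (14, -0.01, 0.482) or CD8 T cell marker (8, -0.08, 0.432) list passed, nor did any adjusted over the list alone. The larger differences there included Atp5o (0.45), Hspa1a (-0.32) and Cd8b1 (-0.34).

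Markers of other cell types were low or mixed. Of 8 myeloid markers kept, Fcer1g alone rose (1 rose and 2 fell adjusted over the list alone, median -0.41, camera adjusted p = 0.189). Of 5 CD4 and regulatory T cell markers 1 rose and 2 fell, Il2ra at -1.27 among them (median -0.60, camera adjusted p = 0.107), and of 3 NK markers 0 passed (1 rose and 1 fell adjusted over the list alone, median -0.30, camera adjusted p = 0.482). Of 3 tumour and stroma markers Vim rose (1.18) and Igfbp7 (-2.36) and Pecam1 (-0.89) fell (median -0.89, camera adjusted p = 0.186). No B cell or neutrophil marker was kept (highest 0.5 FPKM for Cd22 and 0.63 for G0s2), and the erythroid list kept Alas2 alone (highest 1.34 FPKM).

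Across the transcriptome 1278 of 9782 genes differed between the wild-type subsets, 708 higher and 570 lower in term-diff, of which 197 and 198 at least doubled or halved. The balance turned under other scalings, with 654 higher and 744 lower after median-of-ratios scaling, 652 and 717 after quantile normalization, 76 and 82 after rescaling, and 910 and 973 with voom. It also turned without wild-type stem-like replicate 1 (276 and 332). The count was 608 and 766 without wild-type stem-like replicates 1 and 2, and 675 and 646 without wild-type term-diff replicates 1 and 2. Without both replicate 2 libraries, whose small RNA held 63.2% and 56.0% of the FPKM against 77.9% to 84.4% in the other 6, it was 325. Of the 1278 genes 291 were called then, and Mki67, Mcm5 and Pecam1 were not. Rescaling each library to an equal sum, which shifted the median of all genes by 0.155, left 158, and the count was 752 without a filter and 756 with these 4 libraries alone in the fit.

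Between the Cd69-deficient subsets part of the leading genes were the same. Tcf7 fell from 50.6 ± 14 to 0.302 ± 0.1 FPKM (-5.28 ± 0.19, adjusted p = 2.1e-05), with Slamf6 (-4.16), Dapl1 (-4.04) and Ccr7 (-3.98). Havcr2 (3.51), Fcer1g (3.51), Entpd1 (3.21) and Gzmb (49.4 ± 0.2 to 399 ± 58 FPKM, 2.98 ± 0.17, adjusted p = 6.3e-05) rose. So did Filip1 (3.05), Ccl5 (2.92), Gzmf (2.87), Gzmd (2.58) and Ppp1r3b (2.57). Further falls were Lrig1 (-3.33), Aff3 (-3.22), the progenitor transcription factor Myb (-2.84), Tespa1 (-2.83), Cyr61 (-2.83) and Emb (-2.69). Gzmd, Gzme and Gzmf are close paralogs, so which of them gained reads is uncertain. Cd69 itself was at 3.05 ± 0.9 and 2.32 ± 0.16 FPKM (-0.27 ± 0.17, adjusted p = 0.38).

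Of 19 stem and progenitor genes 14 fell and 0 rose in the Cd69-deficient cells (17 fell adjusted over the list alone, median -1.28), with camera adjusted p = 8.3e-16 and adjusted p = 0.245 with an estimated correlation. Terminal exhaustion genes rose in 11 of 22 cases and fell in 1 (11 and 2 adjusted over the list alone, median 0.44), among them Id2 (1.80), a regulator of effector cells. For these camera gave adjusted p = 1.52e-07, and adjusted p = 0.245 with an estimated correlation. In the cytotoxic list 10 of 23 rose and 2 fell (12 and 3 adjusted over the list alone, median 0.48), with camera adjusted p = 6.21e-05 and adjusted p = 0.245 with an estimated correlation. Egress genes fell in 8 of 15 cases, with 0 higher (10 fell and 2 rose adjusted over the list alone, median -0.98), with camera adjusted p = 1.29e-06 and adjusted p = 0.245 with an estimated correlation. Of 14 residency genes 5 rose, such as Itga1 (1.74), and 2 fell (5 and 2 adjusted over the list alone, median 0.42). Their camera adjusted p = 0.0095 became adjusted p = 0.288 with an estimated correlation.

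In the proliferation list of the Cd69-deficient cells 0 of 29 passed (0 adjusted over the list alone), yet 28 lay above 0, with a median of 0.28 and Stmn1 at 0.60. Camera adjusted p = 1.56e-05 stood beside adjusted p = 0.392 with an estimated correlation. Oxidative phosphorylation genes rose in 7 of 35 cases, with 0 lower (9 rose adjusted over the list alone, median 0.39), such as the subunits Sdhb (0.74) and Cox7c (0.93). That list had camera adjusted p = 3.97e-07, and adjusted p = 0.245 with an estimated correlation. Glycolysis had 1 higher and 1 lower of 18 (6 and 1 adjusted over the list alone, median 0.25), with camera adjusted p = 0.0257 and adjusted p = 0.392 with an estimated correlation.

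The remaining lists did not pass there by camera. By fry the early T cell receptor response (adjusted p = 0.0481) and chemokine and cytokine lists (adjusted p = 0.0457) leaned down. So did markers of CD4 and regulatory T cells (fry adjusted p = 0.00199) and of tumour and stroma (fry adjusted p = 0.0481). Early T cell receptor response genes had 1 of 26 up and 7 down (1 and 8 adjusted over the list alone, median -0.18, camera adjusted p = 0.0768), with Cd83 at -2.49 and Jun at -1.19. Chemokines and cytokines had 5 of 18 up and 6 down (6 and 9 adjusted over the list alone, median -0.23, camera adjusted p = 0.608), and the osteopontin gene Spp1 rose (1.75). CD8 T cell markers had 0 of 8 (0 adjusted over the list alone, median 0.18, camera adjusted p = 0.105). Heat shock had 0 of 14 up and 1 down (0 and 1 adjusted over the list alone, median -0.16, camera adjusted p = 0.581), and interferon response 0 of 24 up and 1 down (0 and 0 adjusted over the list alone, median 0.02, camera adjusted p = 0.598).

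Markers of other cell types were again mixed between the Cd69-deficient subsets. Of 8 myeloid markers 1 rose, Fcer1g, and 1 fell (1 and 3 adjusted over the list alone, median -0.38, camera adjusted p = 0.612). Of 5 CD4 and regulatory T cell markers 0 rose and 2 fell, Il2ra (-1.24) among them (0 and 2 adjusted over the list alone, median -0.29, camera adjusted p = 0.201). Of 3 NK markers 1 rose, Klre1 (1.12), and 1 fell (1 and 1 adjusted over the list alone, median -0.11, camera adjusted p = 0.827). Of 3 tumour and stroma markers 1 rose, Vim (0.96), and 2 fell, Pecam1 (-1.34) among them (1 and 2 adjusted over the list alone, median -1.25, camera adjusted p = 0.283). The Vim call ended without Cd69-deficient stem-like replicate 1 (adjusted p = 0.0553) or 2 (adjusted p = 0.0523) or term-diff replicate 2 (adjusted p = 0.0529).

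In all, 924 genes differed between the Cd69-deficient subsets (380 higher and 544 lower in term-diff, 138 and 187 at least doubled or halved). The count was 289 and 413 without Cd69-deficient stem-like replicates 1 and 2, and 420 and 363 without Cd69-deficient term-diff replicates 1 and 2. It was 87 after rescaling (median shift -0.305), 545 without a filter and 1634 with voom. The Sdhb call ended without Cd69-deficient stem-like replicate 1 (adjusted p = 0.0968) or term-diff replicate 1 (adjusted p = 0.0735), and that of Cox7c without any 1 of these 4 libraries (adjusted p = 0.0677 to 0.2). The glycolysis list call ended without stem-like replicate 1 (adjusted p = 0.0767) or term-diff replicate 2 (adjusted p = 0.0702).

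Many subset differences were shared by the genotypes. Of the genes called in each, 640 were called in both in the same direction, 257 higher and 383 lower. If the calls were independent, 28 and 32 would be shared. Fold changes over all genes correlated with r = 0.49 (Spearman 0.54). The 2 comparisons share no library but use the same estimate of the spread per gene, which can raise the number of shared calls.

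**Figure D2:**
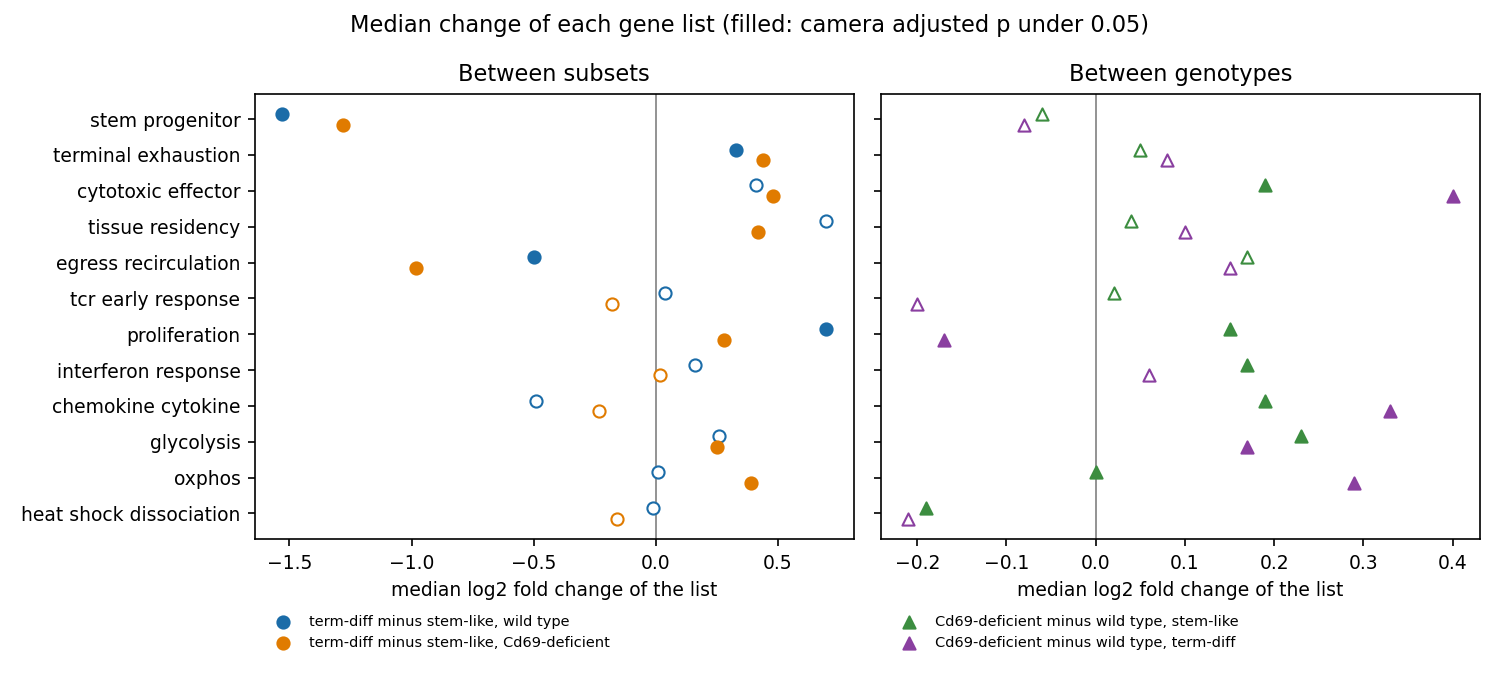
Median log2 fold change of the members of each gene list in each comparison. Filled markers have a camera adjusted p under 0.05 at the preset correlation, and 0 of these calls held with an estimated correlation.

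Few genes were called by genotype in stem-like cells. Erdr1, a gene of the pseudoautosomal region, rose from 51.5 ± 3.2 to 397 ± 93 FPKM (2.90 ± 0.26, adjusted p = 0.0056), and Csf1, a macrophage growth factor, from 12 to 24.4 (0.96 ± 0.13, adjusted p = 0.042). Besides Cd69, Klrc3 fell from 45.5 to 8.81 (-2.24 ± 0.22, adjusted p = 0.0096), a receptor of the NKG2 family, and the glutamate transporter Slc1a2 from 6.93 to 1.35 (-1.76 ± 0.18, adjusted p = 0.011). The cell junction protein Pkp4 (28.6 to 13.3, -1.05 ± 0.14), Ccr6 (-1 ± 0.13) and Mmd (15.8 to 7.6, -0.97 ± 0.13) fell, each with adjusted p = 0.042. Klra3 (-1.24, adjusted p = 0.032) and Defb13 (-2.01, adjusted p = 0.0019) also passed, the latter listed at 0 in Cd69-deficient and resting on 1 implied fragment per wild-type library. Klrc3 and Klra3 belong to families of near-identical genes, so their reads may be shared with paralogs.

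The set fixed for the genotype comparisons did not pass in stem-like cells. Tcf7 was at -0.26 (adjusted p = 0.83), Havcr2 at 0.72 (adjusted p = 0.22) and Gzmb at 0.91 ± 0.17 (adjusted p = 0.16). Slamf6 was at 0.41, Pdcd1 -0.10, Tox -0.40, Ifng 0.17 and Klf2 0.37, and S1pr1 lay below the filter (0.04 to 1.64 FPKM). Of 25 alternatives Gzmb passed in 4 (lowest adjusted p = 0.00095, with voom). No cytotoxic effector gene passed in this comparison (1 of 23 rose adjusted over the list alone), but 21 of 23 lay above 0, with a median of 0.19, Prf1 at 0.59 and Klrd1 at 0.57. Camera gave adjusted p = 0.0066 here, and adjusted p = 0.569 with an estimated correlation. Of 18 chemokine and cytokine genes Csf1 rose (4 adjusted over the list alone, median 0.19), with camera adjusted p = 0.0286 and adjusted p = 0.569 with an estimated correlation.

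Some lists leaned to 1 side by genotype in stem-like cells with no member past the threshold. Glycolysis genes (0 of 18, 0 adjusted over the list alone, median 0.23) had camera adjusted p = 0.00112 and adjusted p = 0.569 with an estimated correlation, with Slc2a1 at 0.43 and Aldoa at 0.39. The proliferation list leaned up (median 0.15), with camera adjusted p = 0.016 and adjusted p = 0.754 with an estimated correlation. So did interferon response (0.17), with camera adjusted p = 0.0294 and adjusted p = 0.868 with an estimated correlation, and CD8 T cell markers (0.14), with camera adjusted p = 0.0432 and adjusted p = 0.754 with an estimated correlation. Heat shock genes leaned down (median -0.19), although 1 was higher and 0 lower adjusted over the list alone, with camera adjusted p = 0.0294 and adjusted p = 0.754 with an estimated correlation. Oxidative phosphorylation had 17 genes above and 18 below 0, a median of 0 and a mean of -0.06 (camera adjusted p = 0.0432, adjusted p = 0.754 with an estimated correlation). Stem and progenitor genes (median -0.06, camera adjusted p = 0.477, 4 up and 4 down adjusted over the list alone), terminal exhaustion (0.05, 0.867), residency (0.04, 0.739), egress (0.17, 0.331) and early T cell receptor response genes (0.02, 0.957) did not pass. Ikzf2, the factor Helios, was at -0.98 and the chromatin organizer Satb1 at 0.79.

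Single libraries ended several of these list calls. The cytotoxic call ended without wild-type stem-like replicate 2 (adjusted p = 0.098), and the chemokine call without that library (adjusted p = 0.275) or Cd69-deficient stem-like replicate 1 (adjusted p = 0.062). Proliferation lost its call without wild-type (adjusted p = 0.102) or Cd69-deficient stem-like replicate 2 (adjusted p = 0.976). For interferon response it was wild-type stem-like replicate 2 (adjusted p = 0.176) or Cd69-deficient stem-like replicate 1 (adjusted p = 0.983). Heat shock depended on stem-like replicate 1 of wild type (adjusted p = 0.956 without it) and of Cd69-deficient (adjusted p = 0.464). Oxidative phosphorylation depended on the same 2, and its call also ended without either wild-type term-diff library. Term-diff libraries enter this comparison only through the shared spread, so leaving 1 out does not move its fold changes. The call of CD8 T cell markers ended without wild-type stem-like replicate 1 (adjusted p = 0.387), either Cd69-deficient stem-like library (adjusted p = 0.179 and 0.087) or wild-type term-diff replicate 2 (adjusted p = 0.0504). After rescaling, camera adjusted p = 0.323 for the cytotoxic and 0.616 for the glycolysis list.

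In total 15 of 9782 genes differed by genotype in stem-like cells (4 higher, 11 lower, 3 and 8 at least doubled or halved, and 710 at an unadjusted p under 0.05). Of the calls 26.7% were higher, against 14.3% after quantile normalization and 56.1% after rescaling. The count was 4 and 7 without Cd69-deficient stem-like replicates 1 and 2, 57 after rescaling (median shift -0.472), 5 with a pseudocount of 0.1, 35 with a robust fit and 43 with voom. Leaving out any 1 of the 8 libraries ended the calls of Csf1, Ccr6 and Mmd (adjusted p = 0.0578 to 0.379). Those of Pkp4 and Klra3 ended without any 1 but wild-type term-diff replicate 2 (adjusted p = 0.0502 to 0.346). Slc1a2 lost its call without wild-type stem-like replicate 1 (adjusted p = 0.0758) or 2 (adjusted p = 0.0528) or Cd69-deficient stem-like replicate 1 (adjusted p = 0.134), and Erdr1 (adjusted p = 0.0627) and Klrc3 (adjusted p = 0.134) without the last of these.

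In term-diff cells Erdr1 again rose with Cd69 deficiency (45.4 ± 16 to 196 ± 0.39 FPKM, 2.13 ± 0.26, adjusted p = 0.027), with the granzyme Gzmd (0.876 to 7.11, 2.11 ± 0.24, adjusted p = 0.026). Further rises were the interferon-induced membrane protein Ifitm3 (1.81, adjusted p = 0.041), BC021614 (1.60, adjusted p = 0.017) and the early response gene Ier3 (1.53, adjusted p = 0.042). The NKG2 family receptor Klrc2 (1.35, adjusted p = 0.027) and Gmfg (0.88, adjusted p = 0.042) rose too. Beside Cd69, Klra3 fell from 4.82 to 0.0293 FPKM (-2.50 ± 0.15, adjusted p = 0.0012), a call kept on leaving out any 1 library. The protease Tmprss6 (-1.60, adjusted p = 0.0084), Pkp4 (-0.99, adjusted p = 0.042) and Mmd (-0.95, adjusted p = 0.042) fell. Gzmd, Ifitm3, Klrc2 and Klra3 have close paralogs, so which member changed is uncertain. In the fixed set Tcf7 was at -0.34, Slamf6 -0.08, Havcr2 0.49 (adjusted p = 0.22), Pdcd1 0.04 and Tox -0.55. Gzmb was at 0.51 (adjusted p = 0.26), Ifng 0.56 and Klf2 -0.78, and 0 of the set passed.

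Of 23 cytotoxic genes 1 rose and 0 fell in term-diff cells (11 and 1 adjusted over the list alone, median 0.40), with camera adjusted p = 6.58e-08 and adjusted p = 0.211 with an estimated correlation. CD8 T cell markers had 0 of 8 past the threshold (5 higher adjusted over the list alone, median 0.65), with the T cell receptor chain Cd3d at 0.86 and Cd8b1 at 0.88. Their camera adjusted p = 2.16e-05 became adjusted p = 0.41 with an estimated correlation. Oxidative phosphorylation leaned up (0 of 35, median 0.29), with camera adjusted p = 2.36e-07 and adjusted p = 0.377 with an estimated correlation. Chemokines and cytokines did too (0 of 18, 4 up and 1 down adjusted over the list alone, median 0.33), with camera adjusted p = 0.00406 and adjusted p = 0.211 with an estimated correlation. Glycolysis followed (0 of 18, 1 up adjusted over the list alone, median 0.17), with camera adjusted p = 0.00406 and adjusted p = 0.41 with an estimated correlation. Spp1 was at 1.28 and the glucose transporter Slc2a3 at 0.72. Proliferation genes leaned down (0 of 29, median -0.17), with camera adjusted p = 0.0144, adjusted p = 0.673 with an estimated correlation, and Mki67 at -0.48.

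The stem and progenitor (median -0.08, camera adjusted p = 0.7), terminal exhaustion (0.08, 0.0872), egress (0.15, 0.677) and heat shock lists (-0.21, 0.0872) did not pass by genotype in term-diff cells. Nor did residency, whose median was 0.10 and mean -0.03 (camera adjusted p = 0.829), or interferon response (median 0.06, camera adjusted p = 0.0998). Of 26 early T cell receptor response genes Ier3 alone rose and 0 fell (2 and 2 adjusted over the list alone), while 17 lay below 0 (median -0.20, camera adjusted p = 0.44). The proliferation call ended without Cd69-deficient term-diff replicate 1 (adjusted p = 0.938) and the glycolysis call without wild-type term-diff replicate 2 (adjusted p = 0.107). After quantile normalization camera adjusted p = 0.19 for CD8 T cell markers and 0.0711 for chemokines.

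Altogether 19 genes passed in term-diff cells (11 higher, 8 lower, 9 and 6 at least doubled or halved, and 1481 at an unadjusted p under 0.05). As deposited 57.9% of the calls were higher, against 46.2% after median-of-ratios scaling and 33.3% after quantile normalization. The count was 10 without either Cd69-deficient stem-like library, 7 without wild-type term-diff replicate 2, and 4 and 3 without Cd69-deficient term-diff replicates 1 and 2. It was 3 at 5 FPKM or more, 68 after rescaling (median shift -0.922, with Gmfg at -0.16, above that shift), 78 with a robust fit and 340 with voom. The calls of Gmfg, Mmd and Pkp4 ended without any 1 of the 8 libraries (adjusted p = 0.0551 to 0.328), and those of Ier3, Ifitm3 and Klrc2 without any but the wild-type stem-like ones (adjusted p = 0.0568 to 0.308). Gzmd and BC021614 lost theirs without any 1 term-diff library (adjusted p = 0.0505 to 0.219). Erdr1 lost its call without wild-type term-diff replicate 1 (adjusted p = 0.0578) or either Cd69-deficient one (adjusted p = 0.158 and 0.219), and Tmprss6 without either Cd69-deficient term-diff library (adjusted p = 0.0505 and 0.0729).

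Averaged over subsets, with 4 libraries per genotype, the largest changes with genotype included Cd69 (-2.25 ± 0.12, adjusted p = 0.00025) and Erdr1 (2.52 ± 0.18, adjusted p = 0.0014). Klra3 (-1.87 ± 0.1, adjusted p = 0.00025) and C530028O21Rik (-1.89 ± 0.15, adjusted p = 0.0021), both within 10 Mb of Cd69, fell too. Receptors encoded beside Cd69 moved in both directions. Klrc3 fell (-1.60, adjusted p = 0.0041), while Klrc1 (1.04, adjusted p = 0.023), Klrc2 (1.02, adjusted p = 0.011) and their partner chain Klrd1 (0.83, adjusted p = 0.036) rose, with the division of reads among the Klrc paralogs uncertain. The collagen receptor Mrc2 (-1.56), Pkp4 (-1.02), Mmd (-0.96), Pcyt1a (-0.72), an enzyme of phosphatidylcholine synthesis, and Lyar (-0.53) fell. Ifitm1 (2.05), Ifitm3 (1.33), BC021614 (1.2), Ier3 (1.12) and Gmfg (0.63) rose, where Ifitm1 and Ifitm3 are paralogs. Among stem and progenitor genes Satb1 (0.70) and the interleukin 7 receptor Il7r (0.82) rose and Ikzf2 (-0.96 ± 0.11) fell, and the cytoskeletal gene Vim, which was on the stroma list, rose (0.79). Gzmb was at 0.71 (adjusted p = 0.053), Havcr2 at 0.61 (adjusted p = 0.057), Tcf7 -0.30, Slamf6 0.17, Pdcd1 -0.03, Tox -0.48, Ifng 0.36 and Klf2 -0.21, and 0 of these passed. Gzmb did pass in 8 of 25 alternatives (lowest adjusted p = 3.39e-05, with voom) and Havcr2 in 7 of 25 (lowest adjusted p = 0.0117, with voom).

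Of 23 cytotoxic genes 2 rose averaged over subsets, Klrd1 and Gzmd (1.10), and 0 fell (12 and 1 adjusted over the list alone, median 0.35), with camera adjusted p = 1.04e-08 and adjusted p = 0.147 with an estimated correlation. Klrd1 lies 0.32 Mb from Cd69, and the list member Klrk1 (0.40, not called) also lies within 10 Mb of it. Csf1 (0.71) was the 1 of 18 chemokines and cytokines that rose (7 up and 1 down adjusted over the list alone, median 0.23), with camera adjusted p = 0.000796 and adjusted p = 0.147 with an estimated correlation. Slc2a3 (0.55) was the 1 of 18 glycolysis genes that rose (2 adjusted over the list alone, median 0.21), and lies with 2 others of the list within 10 Mb of Cd69, with camera adjusted p = 3.32e-05 and adjusted p = 0.302 with an estimated correlation. CD8 T cell markers leaned up (0 of 8, 4 up adjusted over the list alone, median 0.42), with camera adjusted p = 3.32e-05 and adjusted p = 0.438 with an estimated correlation. Interferon response did so too (0 of 24, 1 up adjusted over the list alone, median 0.12), with camera adjusted p = 0.0104 and adjusted p = 0.772 with an estimated correlation. Oxidative phosphorylation had a median of 0.10 (0 of 35) and heat shock one of -0.18 (0 of 14), each with camera adjusted p = 0.0104 and adjusted p = 0.644 with an estimated correlation. Terminal exhaustion (median 0.07, camera adjusted p = 0.161), stem and progenitor (-0.01, 0.832), residency (0.06, 0.832), egress (0.15, 0.484), proliferation (-0.04, 0.758) and early T cell receptor response (-0.02, 0.563) did not pass.

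Of these averaged list calls, that of interferon response ended without Cd69-deficient stem-like replicate 1 (adjusted p = 0.308), wild-type term-diff replicate 2 (adjusted p = 0.386) or Cd69-deficient term-diff replicate 1 (adjusted p = 0.113). Oxidative phosphorylation lost its call without any 1 replicate 2 library (adjusted p = 0.0719 to 0.303), and heat shock without any 1 replicate 1 library (adjusted p = 0.0828 to 0.24). Rescaling ended the calls of chemokines (adjusted p = 0.0916), glycolysis (adjusted p = 0.524) and CD8 T cell markers (adjusted p = 0.374).

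Averaging gave 53 genes (26 higher, 27 lower, 11 and 11 at least doubled or halved, and 1212 at an unadjusted p under 0.05). The count was 27 without wild-type stem-like replicate 2, 20 and 17 without Cd69-deficient stem-like replicates 1 and 2, 28 without wild-type term-diff replicate 2, and 29 and 19 without Cd69-deficient term-diff replicates 1 and 2. It was 82 after rescaling, 102 with a robust fit, 13 without a filter and 239 with voom. Cd69, Erdr1 and Pkp4 passed in 25 of 25 alternatives, Klra3 and C530028O21Rik in 24 of 24, Klrc3 and Mmd in 24 of 25, and BC021614 in all but 2. Each other gene named above as risen or fallen was lost on leaving out 3 or more single libraries (adjusted p = 0.0504 to 0.179). Rescaling moved the median of all genes by -0.697 and put Satb1 at -0.07, Gmfg at -0.15, Csf1 at -0.07, Slc2a3 at -0.19 and Vim at -0.01, all above that shift.

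The 2 genotype comparisons had 8 called genes in common in the same direction: Cd69, Erdr1, Klra3, Mmd, Pkp4, 2610005L07Rik, C530028O21Rik and G530011O06Rik. Of these 2 were higher and 6 lower, where 0.0045 and 0.009 would be shared if the calls were independent. Cd69 is among them by the design of the knockout. The 2 comparisons share no library but use the same estimate of the spread per gene, which can raise the number of shared calls. Over all genes their fold changes correlated with r = 0.27 (Spearman 0.14), which was 0.08 without wild-type stem-like replicate 2 or without wild-type term-diff replicate 2, 0.14 without Cd69-deficient stem-like replicate 2, and -0.02 without both wild-type replicate 2 libraries. Like those of Mmd and Pkp4, the calls of the 3 unnamed models within a subset ended on leaving out single libraries, among them either Cd69-deficient library of the subset compared (adjusted p = 0.114 to 0.346). Averaged over subsets these 3 kept their calls, 2610005L07Rik in 25 of 25 alternatives and C530028O21Rik and G530011O06Rik in 24 of 24 each.

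No gene of 10 or more implied fragments in 2 libraries was called in the interaction of genotype and subset. The test called 3 genes, each from at most 4 implied fragments in any library: Defb13 (2.01 ± 0.21), Mir133a-2 (5.89 ± 0.19) and Rnu73b (-10.34 ± 0.81). Among the next smallest p values were those of AY761184 (1.74, adjusted p = 0.16) and, each with adjusted p = 0.3, Slc1a2 (1.55), Klra3 (-1.26), Ccr6 (1.12), Gzmd (2.03), Morn3 (-1.86) and Tmprss6 (-1.07). Ndufa7 (1.39) and Serp2 (1.33) ranked after these, and Cd69 was at 0.66, all with adjusted p = 0.54. Of the lists, oxidative phosphorylation had a median of 0.34 (0 of 35, 0 adjusted over the list alone), with Uqcrb at 1.0, camera adjusted p = 7.12e-09 and adjusted p = 0.803 with an estimated correlation. Proliferation had -0.38 (0 of 29, 0 adjusted over the list alone), with Mki67 at -0.77, camera adjusted p = 0.000179 and adjusted p = 0.803 with an estimated correlation. Cytotoxic genes had 0.10 (0 of 23, 3 up adjusted over the list alone), with camera adjusted p = 0.00695 and adjusted p = 0.803 with an estimated correlation. CD8 T cell markers had 0.19 (0 of 8, 1 up adjusted over the list alone), with Cd3d at 0.71, camera adjusted p = 0.0114 and adjusted p = 0.803 with an estimated correlation.

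Of 9782 genes 889 had an unadjusted p under 0.05 in the interaction, and 0 passed with voom or among genes with at least 10 implied fragments in 2 libraries. Instead of 3, 11 passed without either wild-type stem-like library, 5 and 8 without wild-type term-diff replicates 1 and 2, and 6 without Cd69-deficient term-diff replicate 1. Rescaling gave 55 (median shift -0.461), with 38.2% of calls higher against 66.7%, and 50% after quantile normalization. The Defb13 call ended without any 1 library but wild-type stem-like replicate 1 (adjusted p = 0.059 to 0.255). The proliferation call ended without Cd69-deficient stem-like replicate 2 (adjusted p = 0.0615) or term-diff replicate 1 (adjusted p = 0.163), and the cytotoxic call without the latter (adjusted p = 0.0831). The CD8 T cell marker call ended without wild-type stem-like replicate 2 (adjusted p = 0.241) or either of these 2 Cd69-deficient libraries (adjusted p = 0.0615 and 0.13). Of the 102 list tests over all 6 comparisons 37 passed at the preset correlation, 0 with an estimated correlation and 24 with fry. A call lost with an estimated correlation thus does not set lists apart. Fry passed the stem and progenitor list between wild-type subsets (adjusted p = 0.00226) and the cytotoxic list by genotype averaged over subsets (adjusted p = 0.0207). It passed none of the interaction lists named above (adjusted p = 0.664 or 0.812).

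**Figure D3:**
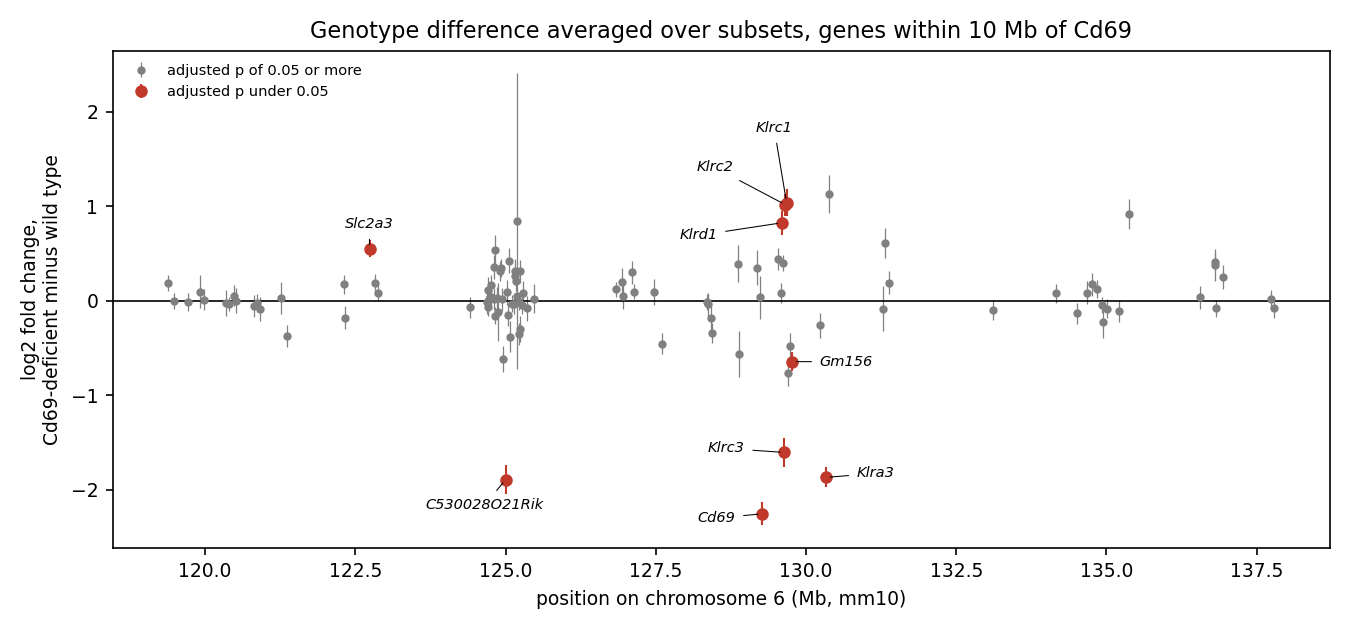
Genotype difference averaged over subsets (log2 fold change ± standard error) of genes within 10 Mb of Cd69 on chromosome 6, with called genes in red. Klrc1, Klrc2, Klrc3 and Klra3 have close paralogs whose reads may be shared.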

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

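Tests of the interaction, a difference of the genotype effect between term-diff and stem-like cells, flagged 7 results here. Of these 3 were genes of few fragments. The other 4 were lists that lost their call with an estimated correlation, as every list did, and did not pass with fry. Of the tests below, the odds ratio near Cd69, the count of genes outside the Klr families, the check of the selected genes, the cytotoxic genes lower in term-diff cells and the fragment counts were chosen only after the result was seen.

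The 3 genes were Defb13 (log2 interaction 2.01), Mir133a-2 (5.89) and Rnu73b (-10.34). Defb13 and Mir133a-2 were listed above 0 in the wild-type stem-like libraries alone, and Rnu73b was listed at 0 there and at 385 to 1560 FPKM in the other 6. Counting noise is a candidate explanation: the highest number of implied fragments of any of them in any library was 4, and of 9434 genes with at least 10 in 2 libraries 0 were called, with 942 at an unadjusted p under 0.05 (limma). The short loci of Mir133a-2 and Rnu73b turn 1 fragment into a large FPKM. A biological difference between the subsets stays open for these genes, since fragments this few cannot exclude it.

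The other 4 were median log2 interactions of gene lists: cytotoxic effector 0.10, proliferation -0.38, oxidative phosphorylation 0.34 and CD8 T cell markers 0.19. Camera with an estimated correlation gave each adjusted p = 0.803. No list passed that test in any comparison, so it does not set these lists apart. By fry CD8 T cell markers had adjusted p = 0.812 and the others adjusted p = 0.664.

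Beside these, 2 patterns were weighed because they bear on what the loss of Cd69 did. The first is the cluster of genotype calls around Cd69 on chromosome 6. Within 10 Mb of Cd69, with Cd69 left out, 8 of 106 genes were called averaged over subsets, against 44 of 9675 elsewhere (odds ratio 17.8, 95% interval 7.07 to 39.7, Fisher's exact p = 7.4e-08). The window was set before the data were examined, as a check for passenger sequence, but the odds ratio was chosen after the calls were seen. Strain sequence carried along with the targeted allele and regulation of neighbouring genes by the loss of CD69, which was not tested, would both raise it and cannot be told apart. Reads shared between the Klra and Klrc paralogs stay open too. By symbol, 3 genes outside the Klr families (Slc2a3 0.55, C530028O21Rik -1.89 and Gm156 -0.64) were called on at least 10 fragments. Gm156 lies between Klri2 and Klra7, so by place it may belong with them. Without any gene of a Klr symbol, but with Gm156 counted, the odds ratio was 7.13 (1.39 to 22.9, Fisher's exact p = 0.011). Leaving out 1 library left C530028O21Rik alone in 7 of 8 cases and Gm156 beside it in the other. Slc2a3 lost its call without any 1 of the 8 libraries (adjusted p = 0.0799 to 0.179) and Gm156 without any but Cd69-deficient term-diff replicate 1 (adjusted p = 0.0893 to 0.161).

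The second is the lean of the cytotoxic list in the Cd69-deficient stem-like libraries, where 0 of 23 genes passed (1 rose adjusted over the list alone) but 21 lay above 0, with a median of 0.19. The camera call of the list was lost with an estimated correlation (adjusted p = 0.569), and fry did not call it (adjusted p = 0.082). Its members Klrd1 and Klrk1 lie within 10 Mb of Cd69. By genotype within term-diff cells the list also leaned up (median 0.40, 19 above 0 and 4 below). Term-diff cells in the stem-like sort could not bring that lean. Term-diff cells carried into the stem-like sort of the Cd69-deficient mice could account for Gzmb and other genes high in those cells: Gzmb needed a share of 9.26% of the term-diff signal, and the median share over 142 other genes high in wild-type term-diff cells was 8.6% (quartiles 1.05 to 18.4), or 7.44% over 106 genes picked in the Cd69-deficient libraries instead. Over the 13 genes with a log2 fold change of at least 2 in both genotypes it was 6.92% (quartiles 3.88 to 7.67), below the share of Gzmb. All these shares were scaled to wild-type term-diff levels. Gzmb was at 285 and 273 FPKM in wild-type and 440 and 358 in Cd69-deficient term-diff libraries. Scaled to the latter its share would be smaller. Such shares were not computed, so this gap decides nothing. Single genes spread widely, from -2.15% for Fcer1g and 0.911% for Ppp1r3b to 13.1% for Ccl5 and 18.3% for Prf1. The ratio of the median over the 142 genes to the share of Gzmb was 0.591 to 1.16 over the 4 pairings of libraries. The 8 cytotoxic genes lower in wild-type term-diff than in stem-like cells would not rise by cells at those wild-type levels. Yet 6 or 7 of them lay above 0 in each pairing (medians 0.15 to 0.18). Srgn, 1 of these, was at 125 and 112 FPKM in the Cd69-deficient term-diff libraries. That was above the 108 and 95.6 of wild-type stem-like, so such cells could raise it. The excess of the 8 genes beyond the share of Gzmb and the median of all genes took the higher of the 2 term-diff levels. Its median was 0.05 to 0.18, with a lower quartile of -0.03 to 0.12, so for them the explanation is neither met nor excluded. Whether the wild-type replicate 2 library standing apart made the difference cannot be told apart from fewer libraries: without both such libraries the list lost its call (adjusted p = 0.0861, range over its alternatives 0.000157 to 0.569), which the bound set beforehand counted for that explanation, but its median was larger (0.26 against 0.19), and for that reason, seen afterwards, it is left undecided. A shift of the stem-like cells themselves toward effector genes was not tested apart from these and stays open.

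Splits of the libraries did not settle whether chance made the calls between the genotypes. The additive model of subset and genotype called 34 genes for the real genotypes, and of 34 splits of the 8 libraries into 4 and 4 that could be fitted, 1, the real one, reached that number; the highest of the others called 2. The bound set beforehand, under 0.05 of the splits reaching that number, was met and counted against chance. At an unadjusted p under 0.05 the real split had 1084 genes and the highest other 1330. The bound did not cover this, and it is left undecided.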

How the results depend on the processing

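Results were recomputed under the alternatives that could be applied to them, and the added ones (small RNA left out, at least 10 implied fragments, both wild-type replicate 2 libraries out, voom, the additive model) were chosen only after the data were seen. Of 988 alternatives for 37 called lists, 831 kept the call, 157 lost it and 0 reversed; of 3523 for 142 called gene results, 2885 kept it, 632 lost it and 6 reversed; of 1331 for 54 gene results not past the threshold, 1242 stayed so, 62 passed and 27 changed sign. The correlation of subset differences stayed between 0.36 and 0.73. All 6 of these reversals came on rescaling to an equal sum, which moved the median of all genes by -0.697 averaged over subsets and by -0.922 in term-diff, and the genes stayed above the moved median. The subset calls of Tcf7, Ccr7, Slamf6, Havcr2 and Gzmb were kept under all alternatives in both genotypes, but of all subset calls rescaling kept 103 of 1278 in wild type and 50 of 924 in Cd69-deficient, and leaving out both wild-type replicate 2 libraries kept 291 of the 1278. With 2 libraries per group, leaving 1 out rests on the assumption that the lone library varies like the other groups. A library outside the groups compared enters only through the shared spread. Leaving it out can end a call but does not move the fold changes of that comparison. Fewer libraries were compared where some were left out; for the filters, scalings, fits and voom the cause of a moved count was not tested. Depth of 2055402 to 2591061 implied fragments per library limits what genes of few fragments can show. Quasi-likelihood tests of read counts were set beforehand for count files and were not run, since the values were FPKM.

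Counts that moved by more than 1.5 times, by setting, were these. Subset difference in wild type (1278): no filter 752, rescaled 158, only the groups compared 756, a log2 fold change of at least 1 395, both wild-type replicate 2 libraries out 325, leave-one-out 608 to 1099. Subset difference in Cd69-deficient (924): no filter 545, rescaled 87, voom 1634, adjusted p under 0.1 1441, a log2 fold change of at least 1 325, leave-one-out 289 to 888. Genotype in stem-like (15): pseudocount 0.1 5, no filter 4, at least 5 FPKM 9, rescaled 57, robust 35, small RNA out 30, at least 10 implied fragments 29, both wild-type replicate 2 libraries out 24, voom 43, leave-one-out 4 to 16. Genotype in term-diff (19): no filter 11, at least 5 FPKM 3, quantile 9, rescaled 68, robust 78, small RNA out 72, at least 10 implied fragments 79, voom 340, adjusted p under 0.1 47, leave-one-out 3 to 21. Genotype averaged (53): no filter 13, at least 5 FPKM 34, rescaled 82, robust 102, small RNA out 110, at least 10 implied fragments 114, both wild-type replicate 2 libraries out 29, voom 239, adjusted p under 0.1 103, a log2 fold change of at least 1 22, additive model 34, leave-one-out 17 to 58. Interaction (3): pseudocount 5 8, rescaled 55, small RNA out 1, at least 10 implied fragments 0 (942 at an unadjusted p under 0.05), both wild-type replicate 2 libraries out 18, voom 0, leave-one-out 2 to 11. List tests (37): rescaled 17, estimated correlation 0, fry 24.

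With the replicate number as a block the counts were 8 in stem-like, 6 in term-diff and 40 averaged over subsets. Whether the replicate numbers pair the libraries is not stated in the labels. Deviations within groups correlated at -0.3 to 0.15 between groups, highest between the wild-type groups, which does not settle it, and the numbers were not used as pairs.

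Signs reversed mostly on rescaling to an equal sum, which follows the small RNA share of each sum. In stem-like these were Slamf6 -0.11, Ifng -0.37, Klf2 -0.12, Slc2a1 -0.06 and Aldoa -0.15. In term-diff they were Gmfg -0.16, Havcr2 -0.55, Pdcd1 -1.03, Gzmb -0.56, Ifng -0.50, Cd3d -0.17, Cd8b1 -0.18 and Slc2a3 -0.28. Averaged over subsets they were Gmfg -0.15, Satb1 -0.07, Vim -0.01, Gzmb -0.09, Havcr2 -0.03, Slamf6 -0.33, Ifng -0.43, Csf1 -0.07 and Slc2a3 -0.19. Quantile normalization reversed Pdcd1 (-0.49) and Gzmb (-0.18) in term-diff. Without both wild-type replicate 2 libraries Pdcd1 averaged over subsets was 0.03 and the correlation of genotype differences -0.02. Leaving out 1 library reversed Hspa1a between wild-type subsets (-0.78 to 0.14), Tcf7 (-0.54 to 0.02) and Klf2 (-0.06 to 0.79) in stem-like, Slamf6 (-0.18 to 0.02) and Pdcd1 (-0.02 to 0.10) in term-diff, and Pdcd1 (-0.08 to 0.02) and Klf2 (-0.42 to 0.01) averaged over subsets.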

Other observations

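The tests and genes in this part were chosen after the results were seen, apart from the list levels.

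Among genes called between the genotypes averaged over subsets, several stood outside the fixed lists. Irf8, a transcription factor induced in activated CD8 T cells, fell (-0.73, 33.5 to 18.2 FPKM in stem-like and 56.3 to 36.6 in term-diff, n = 2 each). Ncf1 (-0.84), a subunit of the phagocyte oxidase, Spry2 (-0.73), a brake on receptor tyrosine kinase signalling, Ddit4 (-0.53), an inhibitor of mTOR signalling, and C1qtnf6 (-0.86) fell as well. Anxa1, an annexin, rose (1.08), as did the galectin Lgals3 (0.96), Siglec5 (0.95), Ctla2a (0.84) and Ms4a4c (0.78). Each of these calls ended on leaving out at least 5 of the 8 libraries singly (adjusted p = 0.051 to 0.18).

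Unnamed gene models called averaged over subsets included 2610005L07Rik (-1.03) and 6820431F20Rik (-1.02), neighbours on chromosome 8, and G530011O06Rik (1.45) on chromosome X, away from Cd69. Tmprss6 was at -1.06 and Klra3 at -1.87 averaged over subsets.

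Replicates correlated over all genes kept with r = 0.906 in wild-type stem-like, 0.95 in Cd69-deficient stem-like, 0.933 in wild-type term-diff and 0.952 in Cd69-deficient term-diff. The first principal component held 31.1% of the variance and placed the stem-like libraries at -39.2 to -7.1 and the term-diff ones at 4.8 to 32. The second held 22.6%, and along it the wild-type replicate 2 libraries lay at -16.8 and -45.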
